A study of Homo sapiens with 24 samples.

How the data were processed

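The 24 samples were arrays of 4 T-ALL lines with DMSO or NVS-ZP7-3 (8 groups of 3). Per the labels' protocols, cells were treated for 16 h at 0.5% DMSO, RNA was isolated with a Qiagen RNeasy Mini kit, and biotin-labelled cRNA was made with the Affymetrix 3' Plus protocol. The authors deposited 1 table of log2 expression values with 54675 probe sets. The submitters' processing notes name GCRMA and limma, without version, order or settings. GCRMA subtracts background with a model of probe sequence, normalizes between arrays and summarises the probes of a set, which puts undetected probe sets at a common floor. From the values, the floor was 2.18 on every array, upper quartiles lay between 8.54 and 8.65 and maxima between 16.1 and 16.2, and 52.4 to 53.9% of the probe sets of an array lay within 0.1 of the floor. No value was missing. The depth of an array has no count, so the number of arrays and the signal over the floor limit the precision.

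Probe sets were named through the platform annotation, which is dated, with symbols updated through the gene identifier in a RefSeq table of assembly GRCh38.p14. Of the probe sets, 41097 had 1 gene, 1801 several and 11777 none, and 41043 of those with 1 gene matched the table while 54 kept the symbol of the annotation. No coordinates are given, since no genome build is named for the values. The probe set with the highest mean over all 24 arrays stood for a gene (19775 genes, 10523 of them with more than 1 probe set), and a gene was tested when that probe set was at log2 4 or more on at least 3 arrays (10661 genes). Genes of chromosome Y and XIST were tested but are not reported.

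A linear model with 8 group means was fitted to all 24 arrays with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit, eBayes; 16 residual and 18.0 total degrees of freedom), so that all groups shared the estimate of spread. The contrasts were the treatment effect in each line, its mean over the lines, its difference from the mean of the other 3 lines, an F test of the interaction and an F test among the DMSO groups. P-values were adjusted by Benjamini-Hochberg over the 10661 genes and called below 0.05. Groups at the floor have a spread near 0 and lower the shared estimate. Standard errors and p-values of genes at the floor in some groups can therefore be too small for the groups that express them. Gene lists were fixed before the files were opened, and the 28 with at least 3 tested members were tested with camera at a preset correlation of 0.01, with an estimated correlation and with fry, adjusted over the 28 lists of a comparison. Camera compares the test statistics of the members of a list with those of all other genes. Fry asks whether the members change in a common direction, without that comparison. The lists of myeloid, erythroid and epithelial markers had 1 tested member each (LYZ, HBB and COL1A1) and were not tested. At the preset correlation 14 lists were called in TALL-1, 9 in SUPT11, 13 in P12-ICHIKAWA, 13 in RPMI-8402 and 15 on average over the lines, and 8, 8, 7, 8 and 11 with the estimated correlation. Calls that were lost are given where they are printed. For calls that held, the p-value printed first is that at the preset correlation, and the estimated correlation could give a far weaker one, as in TALL-1. Overlaps were tested with Fisher's exact test, and lines share no array, though they share the estimate of spread of each gene.

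Genes were named by a rule fixed before the files were opened: the 12 largest rises and falls on average over the lines, the 6 of each per line with no overlap between treated and DMSO arrays, the 10 widest ranges among lines, 3 per line for DMSO levels (all at log2 6 or more in the higher group), up to 4 members per list, and a set of key genes of zinc handling, ER stress, Notch signalling and cell death. Of the key genes, BBC3 had no probe set of its own, and CDKN1A did not exceed 2.19 on any array.

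The steps were tested on simulated arrays with the mean of each line and the residual spread of the real data, and with no treatment effect except in 200 of the 10661 genes per line. At a log2 change of 1, 92.5% were recovered in TALL-1, 88.1% in SUPT11, 94.0% in P12-ICHIKAWA and 92.5% in RPMI-8402. At 0.5 the shares were 49.3, 62.7, 71.6 and 67.2%, with 12, 8, 3 and 9 false calls. The simulated noise was independent between genes, had the same spread in all groups and had no floor. The shares therefore do not show how well changes near the floor are found. Differences in share between lines come from the random draw of genes and noise. Alternatives fixed before the files were opened were other filters, the mean of all probe sets, quantile normalization, median centring, the replicate number as a block, an intensity trend, fits of a line alone, other thresholds and leaving out each array. Alternatives chosen after seeing the data were leaving out 3 arrays with transcripts foreign to their line, and the ACTB 3' to 5' difference or the HBB level as a covariate. Tables were made with Python 3.11.15 and pandas 2.3.3, and figures with matplotlib 3.10.9.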

Results

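Gene expression was measured in 4 human T-cell acute lymphoblastic leukaemia (T-ALL) lines, TALL-1, SUPT11, P12-ICHIKAWA and RPMI-8402, after 16 h with the compound NVS-ZP7-3 or with its solvent DMSO at 0.5%. Each of the 8 combinations of line and treatment had 3 arrays, 24 in all. The labels do not say whether the 3 were separate cultures, so p-values measure the spread between these samples, which may be technical. Compounds of the NVS-ZP7 series have been described as inhibitors of SLC39A7 (ZIP7), a transporter that releases zinc from the endoplasmic reticulum (ER), found through their effect on Notch signalling. The labels give neither a target nor a dose. Expression is given on the deposited log2 scale, on which background lies at a floor of 2.18, so any part of a change below that floor is not seen. Of 19775 genes with a probe set of their own, 10661 passed the filter on low values and were tested with limma.

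Arrays of a group correlated at 0.993 to 0.998 (Pearson, across genes, which are not independent replicates), and arrays of different lines at 0.735 to 0.873. The first 3 principal components carried 45.9, 30.5 and 19.9% of the variance. The difference between the 3' and 5' control probe sets of ACTB, a measure of RNA integrity, was 0.49 higher with NVS-ZP7-3 in TALL-1 and 0.30 higher in RPMI-8402 (two-sided exact permutation p = 0.1 in both, the smallest that 3 arrays against 3 allow). In SUPT11 and P12-ICHIKAWA it differed by 0.048 and 0.044. The same measure for GAPDH moved by at most 0.042 in any line.

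TALL-1 cells treated with NVS-ZP7-3 raised the genes of the integrated stress response and of the ER. DDIT3, which encodes the stress transcription factor CHOP, rose by 3.28 ± 0.14 on the log2 scale (SE, 3 arrays per group; limma adjusted p = 3.48e-12, Benjamini-Hochberg). TRIB3, a pseudokinase induced by CHOP, rose by 4.45 ± 0.16, CHAC1, which degrades glutathione, by 3.88 ± 0.13, and SESN2, a stress-induced sestrin, by 3.76 ± 0.23. Of the targets of ATF4 and CHOP, 20 of 22 measured members rose, 20 adjusted over the list alone and none fell. The camera adjusted p was 1.06e-14, and 7.99e-04 with an estimated correlation. The aminoacyl-tRNA synthetases under ATF4 control rose with them. Of these, 11 of 11 measured members rose, 11 adjusted over the list alone (camera adjusted p = 2.63e-09, and 0.0344 with an estimated correlation). Among them, WARS1 rose by 1.63 ± 0.098 and CARS1 by 1.19 ± 0.074.

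ER chaperones and folding enzymes rose in TALL-1 (18 of 20 measured members rose, 18 adjusted over the list alone; camera adjusted p = 1.54e-11), with CRELD2 at 1.34 ± 0.096 and HSPA5, the main ER chaperone BiP, at 0.40 ± 0.067. The list of XBP1 targets, ER-associated degradation and ER translocation rose as well (18 of 19 measured members rose, 18 adjusted over the list alone; camera adjusted p = 1.06e-14). Its members included SEC24D, a coat protein of ER export, at 1.92 ± 0.14 and EDEM2, which acts on misfolded glycoproteins, at 1.87 ± 0.087. Genes of cholesterol synthesis and uptake rose (11 of 14 measured members rose, 11 adjusted over the list alone). Their camera adjusted p was 4.33e-05, and 0.0344 with an estimated correlation. MVK, mevalonate kinase, changed by 1.48 ± 0.29.

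Notch pathway targets fell in TALL-1 (11 of 13 measured members fell, 11 adjusted over the list alone). Their camera adjusted p was 3.12e-06, and 0.0166 with an estimated correlation. NRARP, a feedback inhibitor of Notch, fell from 11.04 ± 0.15 to 9.14 ± 0.21 (SD, n = 3), and DTX1, HEY1, HES4 and HES1 changed by -1.65 ± 0.33, -1.62 ± 0.10, -1.31 ± 0.25 and -0.88 ± 0.049. HES4 was low in both groups, at 4.03 with DMSO and 2.72 with NVS-ZP7-3. MYC fell from 11.87 ± 0.21 to 10.87 ± 0.16, and NOTCH1 changed by -0.94 ± 0.22. Of the genes of DNA replication and S phase, 20 of 21 measured members fell, 20 adjusted over the list alone (camera adjusted p = 6.96e-12), with CCNE1, cyclin E1, at -1.03 ± 0.091 and MCM2, a helicase subunit, lower at 10.42 ± 0.17 than with DMSO (11.42 ± 0.21, SD). CDC6 was the exception, at 0.33 ± 0.074. Genes of G2/M and mitosis (15 of 22 measured members fell, 16 adjusted over the list alone; camera adjusted p = 7.89e-05) and of ribosome biogenesis (9 of 17 measured members fell, 9 adjusted over the list alone; camera adjusted p = 0.00263) had lower medians, but neither call held with an estimated correlation (adjusted p = 0.112 and adjusted p = 0.152 with an estimated correlation).

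Zinc transporters of the SLC30 and SLC39 families went both ways in TALL-1 (9 of 17 measured members rose, 9 adjusted over the list alone and 2 fell). Their camera adjusted p was 0.00464, and 0.0315 with an estimated correlation. SLC39A7 itself rose from 9.22 ± 0.15 to 10.99 ± 0.087 (SD, n = 3), a change of 1.77 ± 0.10 (limma adjusted p = 1.87e-10). SLC30A1, the zinc exporter of the plasma membrane, rose by 0.62 ± 0.057 and SLC39A10 changed by -0.56 ± 0.062. The metallothioneins, zinc-binding proteins whose genes respond to cytosolic zinc, showed no call as a list (camera adjusted p = 0.526), with MT2A at -0.45 ± 0.12 and MT1X at 0.22 ± 0.091. The largest rises in TALL-1 were in KLHDC7B (7.20 ± 0.10), ISG20 (6.17 ± 0.24), ANG (5.98 ± 0.16), the ubiquitin ligase subunit FBXO32 (5.62 ± 0.17), FGFBP2 (5.38 ± 0.17) and TSC22D3 (5.34 ± 0.23). The largest falls were in PPEF1 (-5.10 ± 0.23), MEGF6 (-3.53 ± 0.46) and GUCY1B1 (-3.29 ± 0.31). In all, 4471 genes were called at an adjusted p below 0.05 (limma, Benjamini-Hochberg), 2377 higher and 2094 lower, and 607 of them changed by at least 1. Centring each array on its median turned this split to 2033 higher and 2545 lower. These changes went with the 0.49 shift of the ACTB 3' to 5' difference, and with that difference as a covariate 3226 genes were called. On treated replicate 2, 7 of 7 genes at the floor in TALL-1 and bright in the other lines were raised, by a median of 2.95, and without the 3 arrays with foreign transcripts 3858 genes were called.

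**Figure D1:**
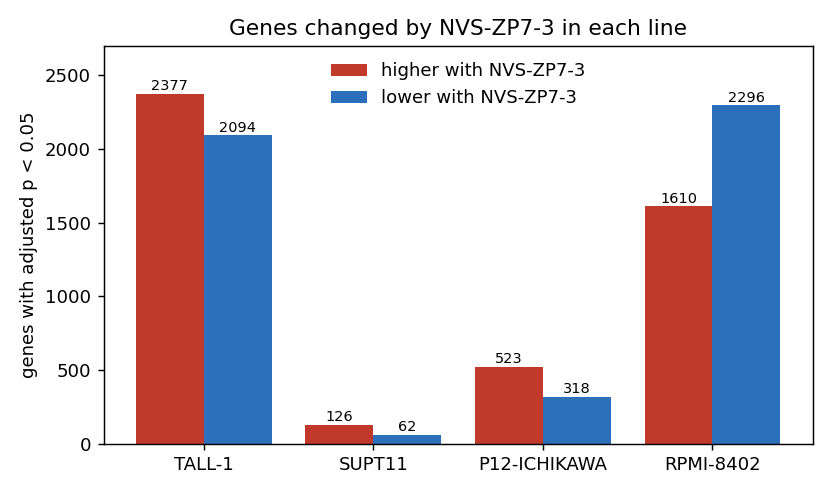
Number of genes called at an adjusted p below 0.05 (limma, Benjamini-Hochberg, of 10661 tested) in each line, drawn from 0, with red bars for genes higher and blue bars for genes lower with NVS-ZP7-3 than with DMSO. TALL-1 had 2377 higher and 2094 lower (2033 and 2545 after centring each array on its median), RPMI-8402 had 1610 and 2296, P12-ICHIKAWA had 523 and 318, and SUPT11 had 126 and 62.

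RPMI-8402 cells showed the same groups of stress and ER genes at a higher level after treatment, and lipid synthesis genes rose more than in the other lines. CHAC1 rose by 5.18 ± 0.13 (limma adjusted p = 7.89e-16, Benjamini-Hochberg), the cystine transporter SLC7A11 by 4.68 ± 0.14, DDIT3 by 4.56 ± 0.14 and TRIB3 by 4.44 ± 0.16. Of the ATF4 and CHOP targets, 19 of 22 measured members rose, 20 adjusted over the list alone (camera adjusted p = 4.05e-21). Of the aminoacyl-tRNA synthetases, 9 of 11 measured members rose, 10 adjusted over the list alone (camera adjusted p = 2.26e-07, but adjusted p = 0.0557 with an estimated correlation). ER chaperones (18 of 20 measured members rose, 18 adjusted over the list alone; camera adjusted p = 1.37e-22) included CRELD2 at 3.05 ± 0.096, SDF2L1 at 2.74 ± 0.17 and HSPA5 at 1.43 ± 0.067. XBP1 targets and ER-associated degradation (18 of 19 measured members rose, 19 adjusted over the list alone; camera adjusted p = 1.36e-20) included HERPUD1, a part of that degradation, at 2.53 ± 0.057.

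All 14 measured genes of cholesterol synthesis and uptake rose in RPMI-8402, over all genes and adjusted over the list alone (camera adjusted p = 1.00e-16). MVK stood at 1.97 ± 0.29, LSS at 1.65 ± 0.078 and HMGCS1, HMG-CoA synthase, at 1.43 ± 0.063. Fatty acid synthesis rose too (8 of 9 measured members rose, 8 adjusted over the list alone; camera adjusted p = 2.22e-06), with ACSS2 at 1.77 ± 0.30 and FASN, fatty acid synthase, at 1.64 ± 0.21.

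Notch pathway targets fell in RPMI-8402 (6 of 13 measured members fell, 7 adjusted over the list alone; camera adjusted p = 3.18e-04). Among them were NOTCH3 at -2.12 ± 0.14, MYC at -1.37 ± 0.10, DTX1 at -2.98 ± 0.33 and HES4 at -1.91 ± 0.25. The last 2 ended near the floor, HES4 going from 4.23 with DMSO to 2.32. Smaller changes were seen in HES1 (11.46 to 11.13) and NOTCH1 (11.95 to 11.57). Ribosome biogenesis and MYC targets fell (14 of 17 measured members fell, 14 adjusted over the list alone; camera adjusted p = 8.84e-07), among them RRP12 at -1.10 ± 0.21 and POLR1B, a subunit of RNA polymerase I, at -0.94 ± 0.075. Cytosolic heat shock proteins fell (8 of 12 measured members fell, 8 adjusted over the list alone; camera adjusted p = 0.00797). In DNA replication and S phase 10 of 21 measured members fell, 12 adjusted over the list alone and 2 rose (camera adjusted p = 0.00827, but adjusted p = 0.270 with an estimated correlation).

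SLC39A7 rose by 1.32 ± 0.10 in RPMI-8402 (limma adjusted p = 1.12e-08), while SLC39A4 changed by -1.60 ± 0.21. Over the zinc transporters 8 of 17 measured members rose, 8 adjusted over the list alone and 2 fell (camera adjusted p = 0.0400, but adjusted p = 0.0866 with an estimated correlation), and the metallothioneins were not called as a list (camera adjusted p = 0.718). Besides the stress genes, the largest rises were in LINC-PINT (4.66 ± 0.17) and ERVFRD-1 (4.51 ± 0.30), and the largest falls in PCDH8 (-5.60 ± 0.09), OLFM4 (-4.70 ± 0.074), MIR646HG (-4.07 ± 0.25), FJX1 (-3.90 ± 0.17), SLC7A2 (-3.83 ± 0.27) and the chemokine receptor CCR9 (-3.73 ± 0.26). In all, 3906 genes were called (limma, Benjamini-Hochberg), 1610 higher and 2296 lower, and 517 changed by at least 1. With the ACTB 3' to 5' difference as a covariate, which was 0.30 higher in treated arrays, 3116 genes were called. Blood cell transcripts were highest on the third DMSO array (HBB at 14.65, LYZ at 12.54), and HBB was also at 9.42, 2.32, 10.48, 8.63 and 12.99 on DMSO arrays 1 and 2 and treated arrays 1, 2 and 3, with LYZ at 4.28, 2.18, 6.25, 4.91 and 9.88.

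P12-ICHIKAWA cells raised stress and ER genes and lowered Notch targets, with fewer genes called. DDIT3 rose by 2.71 ± 0.14 (limma adjusted p = 5.72e-10, Benjamini-Hochberg), TRIB3 by 2.14 ± 0.16 and CHAC1 by 1.81 ± 0.13. XBP1, a transcription factor of the unfolded protein response, rose from 2.68 ± 0.17 to 5.82 ± 0.47 (SD, n = 3). The lists that rose were the ATF4 and CHOP targets (15 of 22 measured members rose, 17 adjusted over the list alone; camera adjusted p = 4.77e-23) and ER chaperones (13 of 20 measured members rose, 15 adjusted over the list alone; camera adjusted p = 1.43e-21). So did XBP1 targets (7 of 19 measured members rose, 10 adjusted over the list alone; camera adjusted p = 4.80e-10) and cholesterol synthesis (5 of 14 measured members rose, 8 adjusted over the list alone; camera adjusted p = 1.57e-05). Among them, ERO1B stood at 2.03 ± 0.14 and STARD4, a cholesterol carrier, at 0.76 ± 0.071.

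DTX1, a Notch target, and NOTCH3, a Notch receptor, had the largest falls in P12-ICHIKAWA, by 3.86 ± 0.33 and 3.09 ± 0.14 on the log2 scale (limma adjusted p = 2.57e-07 and 2.31e-10, each lower in all 3 treated arrays). HES1 changed by -0.53 ± 0.049. Of the 13 Notch targets tested, 3 fell over all genes and 4 adjusted over the list alone (camera adjusted p = 2.06e-04), and MYC, at -0.073 ± 0.10, was not called. DNA replication genes fell (8 of 21 measured members fell, 10 adjusted over the list alone; camera adjusted p = 1.22e-08). Cytosolic heat shock proteins fell as well (1 of 12 measured members fell, 4 adjusted over the list alone; camera adjusted p = 0.00603). The aminoacyl-tRNA synthetases (3 of 11 measured members rose, 4 adjusted over the list alone; camera adjusted p = 2.45e-04), ribosome biogenesis (1 of 17 measured members fell, 1 adjusted over the list alone; camera adjusted p = 0.00322) and the metallothioneins (1 of 6 measured members fell, 2 adjusted over the list alone; camera adjusted p = 0.0389) lost their calls (adjusted p = 0.206, 0.206 and 0.385 with an estimated correlation).

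SLC39A7 stood at -0.02 ± 0.10 in P12-ICHIKAWA and was not called, and SLC30A1 changed by -0.37 ± 0.057. The zinc transporters were not called as a list (camera adjusted p = 0.624). Other large rises were in ERVFRD-1 (2.93 ± 0.30), the protease CTSH (2.73 ± 0.23), the ATP-gated channel P2RX7 (2.37 ± 0.13), LY9 (2.30 ± 0.21) and OPRK1 (2.19 ± 0.25). Further falls were in ARHGAP29 (-1.59 ± 0.11), MIR646HG (-1.54 ± 0.25) and SLC38A10 (-1.52 ± 0.28), for which all 3 other probe sets moved the opposite way on average over the lines. In all, 841 genes were called (limma, Benjamini-Hochberg), 523 higher and 318 lower, and 107 changed by at least 1. HBB stood at 11.45, 8.17 and 7.96 in the 3 treated arrays against 2.18 to 2.29 with DMSO. LYZ, another blood cell gene, averaged 6.37 in them and 2.74 with DMSO, and 388 genes were called with HBB as a covariate. A fit of the 6 arrays of this line alone called 220.

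SUPT11 cells raised ER chaperones and cholesterol genes, while most ATF4 targets that rose in the other lines were not called. HSPA5 rose from 13.07 ± 0.054 to 14.43 ± 0.044 (SD, n = 3; limma adjusted p = 7.04e-10, Benjamini-Hochberg), DDIT3 by 2.51 ± 0.14, XBP1 by 2.21 ± 0.19, SLC7A11 by 1.44 ± 0.14 and SDF2L1 by 1.25 ± 0.17. Of the ER chaperones, 15 of 20 measured members rose, 16 adjusted over the list alone (camera adjusted p = 9.49e-49). Of the cholesterol genes, 10 of 14 measured members rose, 12 adjusted over the list alone (camera adjusted p = 2.96e-34), with STARD4 at 1.14 ± 0.071 and HMGCS1 at 0.79 ± 0.063. The ATF4 and CHOP list was called (4 of 22 measured members rose, 5 adjusted over the list alone; camera adjusted p = 5.39e-09) on DDIT3, CHAC1, SLC7A11 and VLDLR, whereas TRIB3 stood at 0.12 ± 0.16, SESN2 at 0.28 ± 0.23 and ATF3 at -0.019 ± 0.23. XBP1 targets were called as well (4 of 19 measured members rose, 8 adjusted over the list alone; camera adjusted p = 4.37e-12), and the aminoacyl-tRNA synthetases were not (camera adjusted p = 0.0782).

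Notch targets were not called as a list in SUPT11 (camera adjusted p = 0.971; 1 rose and 1 fell, over all genes and adjusted over the list alone). Only 6 of the 13 tested averaged log2 4 or more in SUPT11 with DMSO, against 13 in TALL-1, 9 in P12-ICHIKAWA and 11 in RPMI-8402, and DTX1, NRARP and NOTCH3 lay at the floor there. The median and mean of this list differed in sign in SUPT11. HEY1 was the member that fell (-1.22 ± 0.10). Ribosome biogenesis genes fell as a list (2 of 17 measured members fell, 3 adjusted over the list alone; camera adjusted p = 2.74e-06), with UTP20 at -0.62 ± 0.12. Fatty acid synthesis (0 of 9 measured members rose, 3 adjusted over the list alone; camera adjusted p = 0.00122) and NRF2 targets (1 of 10 measured members rose, 1 adjusted over the list alone; camera adjusted p = 0.00607) were called up, and cytosolic heat shock proteins down (0 of 12 measured members fell, 0 adjusted over the list alone; camera adjusted p = 0.0162, but adjusted p = 0.0875 without the 3 arrays with foreign transcripts). DNA replication genes (camera adjusted p = 0.366), zinc transporters (0.636) and metallothioneins (0.366) were not called, with SLC39A7 at 0.048 ± 0.10.

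The largest rises among genes called in SUPT11 were those of GLUL (4.68 ± 0.45) and CDK6 (3.86 ± 0.79), which were near the floor with DMSO in this line and at 14.47 or above in the others. Both were uneven over the treated arrays, CDK6 at 4.72, 9.53 and 4.35 and GLUL with a mean of 8.05 ± 1.63 (SD, n = 3). RAG1, which was at the floor in SUPT11 with DMSO and at 14.83 in P12-ICHIKAWA, read 4.73, 9.28 and 4.12 on the same arrays, a change of 3.86 ± 1.30 that was not called. On average over the lines, 1 of 2 other probe sets of GLUL and 4 of 5 of CDK6 moved the opposite way. SCRN1 rose by 1.39 ± 0.24. The largest falls were in KIF7 (-1.47 ± 0.18), PLXDC1 (-1.38 ± 0.11), MDS2 (-1.33 ± 0.21), MIPOL1 (-1.33 ± 0.23) and ZIC2 (-1.10 ± 0.21). In all, 188 genes were called (limma, Benjamini-Hochberg), 126 higher and 62 lower, and 40 changed by at least 1. A fit of the 6 arrays of this line alone called 33.

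**Figure D2:**
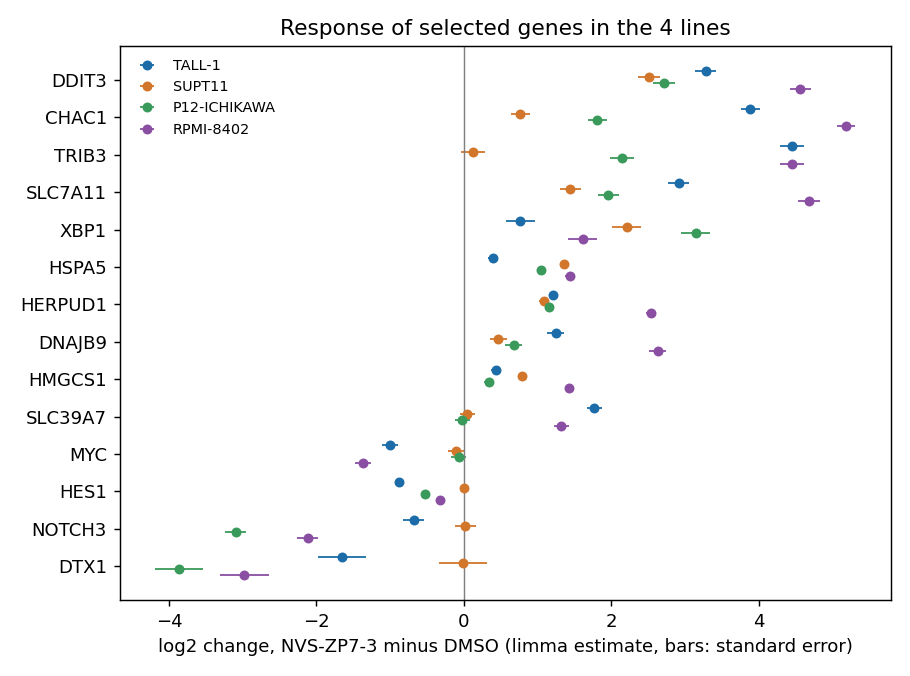
Log2 change (NVS-ZP7-3 minus DMSO, limma estimate, bars for its standard error, 3 arrays per group) of 14 genes, with 1 colour per line. DDIT3 lies between 2.51 and 4.56 in the 4 lines, and DTX1 between -3.86 in P12-ICHIKAWA and -0.012 in SUPT11, where it was at the floor.

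On average over the 4 lines, NVS-ZP7-3 raised genes of the unfolded protein response, the integrated stress response and sterol synthesis, and lowered Notch targets and genes of ribosome biogenesis and DNA replication. DDIT3 rose by 3.27 ± 0.072 (limma adjusted p = 1.16e-16, Benjamini-Hochberg; higher in all 12 treated arrays than in any DMSO array of the same line), CHAC1 by 2.91 ± 0.063, TRIB3 by 2.79 ± 0.081, SLC7A11 by 2.75 ± 0.072, P2RX7 by 2.54 ± 0.063 and XBP1 by 1.93 ± 0.097. TSC22D3 (3.09 ± 0.11), FBXO32 (2.59 ± 0.083) and ISG20 (2.64 ± 0.12) were also among the largest rises. The largest value of all was that of the haemoglobin gene HBB (3.58 ± 1.19), which was at or above log2 4 on 9 of 12 treated and 2 of 12 DMSO arrays and highest on a DMSO array. The largest falls were in DTX1 (-2.13 ± 0.17), LINC01120 (-1.56 ± 0.062), NOTCH3 (-1.47 ± 0.071), SUSD4 (-1.23 ± 0.09), DGAT2, an enzyme of triglyceride synthesis (-1.21 ± 0.10), and CD2 (-1.07 ± 0.067).

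Of the lists, ATF4 and CHOP targets (21 of 22 measured members rose, 21 adjusted over the list alone; camera adjusted p = 1.13e-19), ER chaperones (19 of 20 measured members rose, 19 adjusted over the list alone; camera adjusted p = 8.91e-20) and XBP1 targets (19 of 19 measured members rose, 19 adjusted over the list alone; camera adjusted p = 5.29e-18) rose. Aminoacyl-tRNA synthetases (11 of 11 measured members rose, 11 adjusted over the list alone; camera adjusted p = 1.21e-08) and cholesterol synthesis (14 of 14 measured members rose, 14 adjusted over the list alone; camera adjusted p = 9.89e-13) rose. Notch targets (9 of 13 measured members fell, 9 adjusted over the list alone; camera adjusted p = 9.75e-06), DNA replication (19 of 21 measured members fell, 19 adjusted over the list alone; camera adjusted p = 1.96e-08) and ribosome biogenesis (13 of 17 measured members fell, 13 adjusted over the list alone; camera adjusted p = 3.81e-06) fell. The metallothioneins were not called (camera adjusted p = 0.414), with 1 of 6 measured members lower over all genes and adjusted over the list alone. Zinc transporters were called up (11 of 17 measured members rose, 11 adjusted over the list alone; camera adjusted p = 0.00470), led by SLC39A7 (0.78 ± 0.052), while SLC39A4 (-0.70 ± 0.11) and SLC39A10 (-0.29 ± 0.031) fell. ASNS, asparagine synthetase, was the member of the ATF4 list not called (0.35 ± 0.18). In all, 5001 genes were called (limma, Benjamini-Hochberg), 2391 higher and 2610 lower, of which 106 changed by at least 1. With HBB as a covariate the split turned to 2031 higher and 1842 lower.

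**Figure D3:**
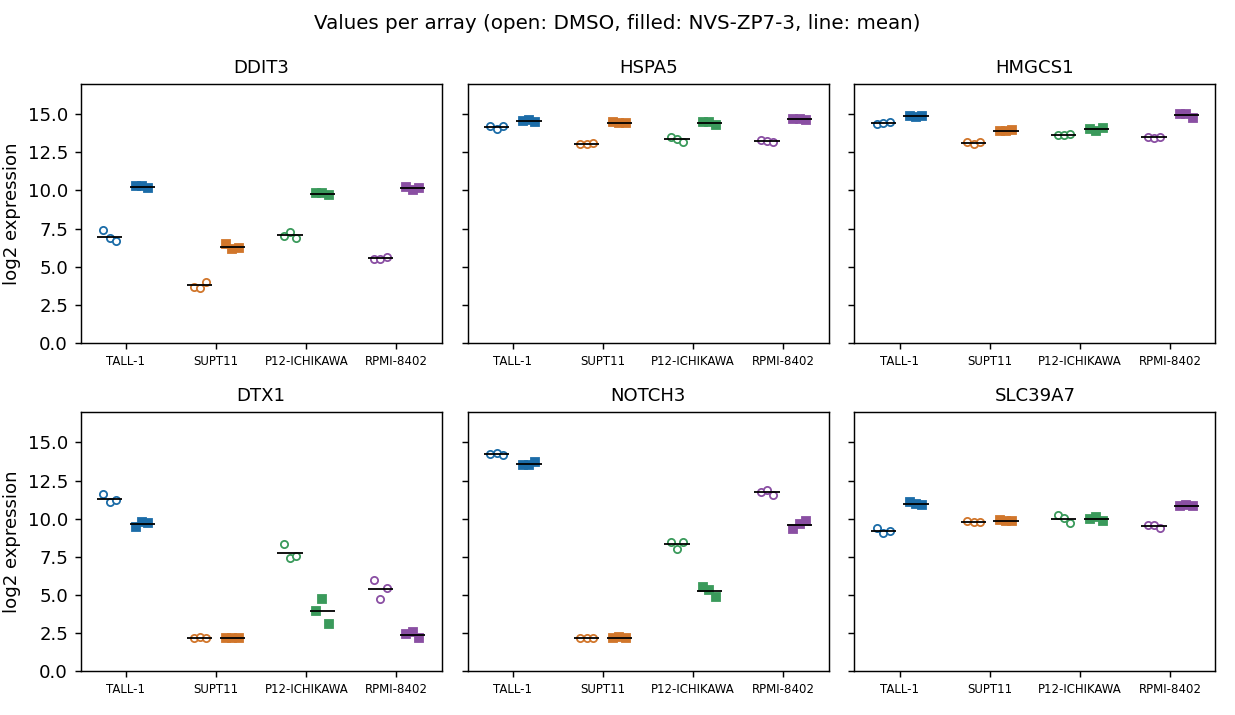
Log2 expression per array of 6 genes in the 4 lines (open circles for DMSO, filled squares for NVS-ZP7-3, short lines for the mean of 3 arrays). In every line the treated arrays lie above the DMSO arrays for DDIT3, HSPA5 and HMGCS1, NOTCH3 and DTX1 lie at the floor of 2.18 in SUPT11, and SLC39A7 differs by 1.77 in TALL-1 and 1.32 in RPMI-8402.

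The lines shared part of their response. A total of 45 genes rose in all 4 lines, where independent lists would share 0.208, among them DDIT3, CHAC1, SLC7A11, VLDLR, XBP1, HSPA5, HERPUD1, DNAJB9, SDF2L1, CRELD2, HYOU1, EDEM1, SEL1L, HMGCS1, MSMO1, STARD4 and the death receptor gene TNFRSF10B. The 3 that fell in all 4 lines were UTP20, SUSD4 and NOP14, the last named after its values were seen (0.0782 expected). TALL-1 and RPMI-8402 shared 993 rises (359 expected from independent lists; two-sided Fisher's exact test, adjusted p = 2.67e-311 over 12 overlaps) and 1050 falls (451 expected, adjusted p = 2.91e-240). SUPT11 and P12-ICHIKAWA shared 51 rises (6.18 expected, adjusted p = 5.62e-34) and 3 falls (1.85 expected, adjusted p = 0.521). Fisher's test treats genes as independent, and the lines share the estimate of spread of each gene, so these p-values can overstate the evidence. Across genes, which are not independent replicates, the changes of TALL-1 and RPMI-8402 correlated with a Pearson r of 0.404 and a Spearman rho of 0.463, and those of TALL-1 and SUPT11 with 0.157 and 0.213.

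The size of the response differed among lines for most members of the stress lists. SUPT11 had lower changes than the mean of the other 3 lines for ATF4 and CHOP targets (18 of 22 measured members lower; median difference -0.90; camera adjusted p = 4.68e-22). The same held for XBP1 targets (15 of 19 lower; median difference -0.54; camera adjusted p = 1.66e-16). Notch targets had a higher value there (9 of 13 higher; median difference 0.71; camera adjusted p = 5.51e-07). Only 6 of these 13 averaged log2 4 or more in SUPT11 with DMSO and members at the floor could not fall, so this value does not show a different response of the pathway. RPMI-8402 had larger rises than the others in cholesterol synthesis (11 of 14 higher; median difference 0.65; camera adjusted p = 6.35e-16). Fatty acid synthesis did so too (6 of 9 higher; median difference 0.51; camera adjusted p = 3.70e-07). TALL-1 had larger falls in DNA replication genes (19 of 21 lower; median difference -0.41; camera adjusted p = 2.43e-11). SLC39A7 differed among the lines (limma F test of the interaction, adjusted p = 2.23e-08), as did MYC (adjusted p = 1.34e-06) and HSPA5 (adjusted p = 2.97e-07).

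Genes with the widest range of the 4 changes were KLHDC7B (range 7.20), ANG (5.98), ISG20 (5.91), FGFBP2 (5.67), PCDH8 (5.60) and CCR9 (5.58), which rose by 1.85 ± 0.26 in TALL-1 and changed by -3.73 ± 0.26 in RPMI-8402. PCDH8 was at the floor in the other 3 lines with both treatments, so the range of PCDH8 shows its expression in RPMI-8402 alone rather than a difference in response. The interaction was called for 3818 genes (limma F test, Benjamini-Hochberg), 1062 of them with a range of at least 1. Against the mean of the other 3 lines, 3050 genes differed in TALL-1 (1797 higher, 1253 lower), 1625 in SUPT11 (764 and 861), 893 in P12-ICHIKAWA (389 and 504) and 1971 in RPMI-8402 (755 and 1216). Centring each array on its median turned the split for TALL-1 to 1462 higher and 1700 lower and that for P12-ICHIKAWA to 530 higher and 490 lower, while SUPT11 and RPMI-8402 kept more genes lower than higher.

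With DMSO, most genes differed among the lines, and some were high in 1 line and near the floor in the other 3. UCHL1 (14.06 ± 0.071, SD, n = 3), PTGDS (13.55 ± 0.08) and TSPYL5 (13.54 ± 0.053) were high in SUPT11 and averaged 2.20 or less in the other 3. TALL-1 stood apart in TSHZ3 (12.48 ± 0.14), the transcription factor MAF (11.67 ± 0.17) and CPA4 (11.43 ± 0.085). P12-ICHIKAWA stood apart in the thymocyte antigens CD1E (13.39 ± 0.096) and CD1B (13.41 ± 0.038) and in LMO2, a T-ALL oncogene (12.37 ± 0.15). RPMI-8402 stood apart in LIMCH1 (13.60 ± 0.018), ATP9A (13.36 ± 0.10) and L1TD1 (13.22 ± 0.084). NOTCH3 averaged 14.25 ± 0.075 in TALL-1, 11.73 ± 0.15 in RPMI-8402 and 8.32 ± 0.25 in P12-ICHIKAWA, and NOTCH1 11.70 ± 0.18, 11.95 ± 0.12 and 10.75 ± 0.14, against 2.45 in SUPT11. In all, 10267 of 10661 genes differed among the 4 lines (limma F test, Benjamini-Hochberg), 6363 of them with a range of at least 1. Line and culture history cannot be separated here.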

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

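All tests of explanations and the lists of foreign transcripts in this part were chosen after the results were seen.

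The change with NVS-ZP7-3 differed among the lines for 3818 genes (limma F test of the interaction). A line differed from the mean of the other 3 for 3050 genes in TALL-1, 1625 in SUPT11, 893 in P12-ICHIKAWA and 1971 in RPMI-8402. These counts include genes at the floor in some lines, which could not fall there. The widest ranges of the 4 log2 changes were 7.20 for KLHDC7B, 5.98 for ANG, 5.91 for ISG20, 5.67 for FGFBP2, 5.60 for PCDH8, 5.58 for CCR9, 5.19 for CHRM3-AS2, 5.12 for FBXO32, 5.10 for PPEF1 and 5.05 for LINC02806. Of the 4 largest, KLHDC7B, ANG, ISG20 and FGFBP2 each had the highest change in TALL-1. PCDH8 outside RPMI-8402 and PPEF1 outside TALL-1 were at the floor with both treatments and could not fall there, so their ranges show expression in 1 line and not a difference in response.

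Gene lists whose response in 1 line differed from the other 3 with both settings of camera are given as the median log2 difference over the members. In SUPT11 these were ATF4 and CHOP targets (-0.90), aminoacyl-tRNA synthetases (-0.40), ER chaperones (-0.27), XBP1 targets (-0.54), Notch targets (0.71) and DNA replication (0.28). The value for Notch targets is limited by the floor, since only 6 of the 13 members averaged log2 4 or more in SUPT11 with DMSO and the rest had little or no room to fall. In P12-ICHIKAWA they were ATF4 and CHOP targets (-0.39), ER chaperones (-0.26), XBP1 targets (-0.37), zinc transporters (-0.053), cholesterol synthesis (-0.34) and fatty acid synthesis (-0.20). In RPMI-8402 they were ATF4 and CHOP targets (0.46), ER chaperones (0.47), XBP1 targets (0.36), cholesterol synthesis (0.65) and fatty acid synthesis (0.51). In TALL-1 they were XBP1 targets (0.49) and DNA replication (-0.41).

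Among 4138 tested probe sets with no gene or several genes, which the comparisons above do not use, 1052 were called in TALL-1, 36 in SUPT11, 108 in P12-ICHIKAWA, 1212 in RPMI-8402 and 1175 on average over the lines (limma, Benjamini-Hochberg).

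GLUL and CDK6, near the floor in SUPT11 with DMSO and bright in the other lines, were higher in treated SUPT11 arrays, most of all in replicate 2. The 9 other genes below 2.5 in SUPT11 and at 12 or above in each other line rose with them on that array, by a median of 1.91 and by over 1 in 7 of 9, which is consistent with RNA of another line as a candidate source on replicate 2. On replicates 1 and 3 their median excess was at most 0.029, which leaves a smaller share of foreign RNA open, since dimmer genes would then stay at the floor. Without replicate 2 CDK6 still changed by 2.19 ± 0.080 and GLUL by 3.74 ± 0.075 (SE, limma adjusted p = 9.06e-12 and 6.69e-16), so a response of SUPT11 cells to the compound cannot be told apart from foreign RNA on these 2 arrays. RAG1, bright in P12-ICHIKAWA and picked after its values were seen, had the same order over the 3 treated arrays (4.73, 9.28 and 4.12), which leaves foreign RNA open on all 3.

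A like set of 7 genes dark in TALL-1 rose by a median of 2.95 on treated TALL-1 replicate 2, in 7 of 7 genes.

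HBB was higher with NVS-ZP7-3 on average over the lines by 3.58 and was present on 9 of 12 treated and 2 of 12 DMSO arrays at log2 4 or more. On RPMI-8402 DMSO replicate 3, where HBB was 14.65, 12 of 14 other blood cell markers exceeded both other arrays of the group by over 1, among them S100A8 at 9.61 and HBD at 8.46, which is consistent with blood cell RNA on that array. On the 6 treated arrays with HBB at 8 or above, a median of 1 other marker exceeded the line's DMSO median by over 1. At most 3 did so (RPMI-8402 replicate 3, with HBB at 12.99, LYZ at 9.88 and MNDA at 4.22). These values were all lower than those on DMSO replicate 3 of that line, where the same markers were raised (LYZ at 12.54, FCGR3B at 11.39 and MNDA at 9.89). LYZ moved with HBB in P12-ICHIKAWA, averaging 6.37 treated against 2.74 with DMSO, but stood at 8.62 on TALL-1 DMSO replicate 2 with HBB at 2.18, which leaves blood cells as the source on treated arrays undecided. A two-sided exact permutation of the treatment labels within lines gave p = 0.0105, but HBB was picked for its large difference, so this test decides nothing, and a response to the compound stays open.

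More genes were called in TALL-1 and RPMI-8402 (4471 and 3906) than in P12-ICHIKAWA and SUPT11 (841 and 188). A larger replicate spread as the cause in SUPT11 is argued against by the median standard deviation within groups, which was lowest there at 0.0786. It was 0.109 in P12-ICHIKAWA, 0.105 in TALL-1 and 0.0977 in RPMI-8402. All groups share the spread of a gene in the fit, so the spread of a line alone does not set its standard errors. With the ACTB 3' to 5' difference as a covariate, 3116 genes were called in RPMI-8402 and 3226 in TALL-1. P12-ICHIKAWA had 939 and SUPT11 had 185. Of the 4471 and 3906 genes called without it, 2787 in TALL-1 and 2779 in RPMI-8402 stayed called. This fit cannot decide on RNA quality, since the covariate is fitted on the scatter within groups. In TALL-1 and RPMI-8402 every treated array exceeded every DMSO array in that difference. RNA quality as read from ACTB therefore cannot be told apart from treatment there. The GAPDH 3' to 5' difference moved by 0.0023 in TALL-1 and 0.042 in RPMI-8402 (two-sided exact permutation p = 0.9 and 0.4). What shifted ACTB but not GAPDH was not tested. The interaction test called 3818 genes, which include genes at the floor in some lines that could not fall there. What made the response differ among the lines, such as the dose that reached the cells, was not tested.

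The counts were set against other splits of the same arrays. In each line the 10 splits of 6 arrays are too few for a share under 0.05, and the real split (1 of 10 in each) called 4471, 188, 841 and 3906 genes in TALL-1, SUPT11, P12-ICHIKAWA and RPMI-8402 against at most 17, 37, 47 and 33 in another split. For the mean over the lines, the real split called 5001 genes against at most 1674 in 100 splits within lines. For the lines with DMSO it called 10267 against 6425 in 100 regroupings. A random grouping of arrays is argued against for the mean over the lines, though the arrays of a group may be technical repeats. The splits within a single line are too few to decide this. The DMSO regroupings mixed arrays of different lines, which differ far more than arrays of a group, so their lower counts add no support. The interaction (3818 against 2690) also exceeded the other splits. So did the differences of SUPT11 (1625 against 88), P12-ICHIKAWA (893 against 643) and RPMI-8402 (1971 against 1801). Splits within lines also remove a treatment effect that the lines share. They therefore cannot decide whether a difference between lines arose by chance. For the difference of TALL-1, 5 of 100 splits, the real one included, called as many genes (3050 against at most 3625), so these splits do not exclude chance. The 4 others had left the arrays of TALL-1 in their real groups and mixed those of other lines, and splits that regrouped TALL-1 itself called at most 195.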

How the results depend on the processing

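Counts of genes, and the calls and signs of named genes and lists, were compared with those of the fit to all 24 arrays. Leaving out the 3 arrays with foreign transcripts and the ACTB and HBB covariates were chosen after seeing the data. The count in each comparison stayed within 1.5 times under other filters, the mean of all probe sets, quantile normalization, median centring, an intensity trend and both replicate blocks. Whether the replicate numbers pair the arrays stayed open. Deviations of same-numbered arrays correlated at -0.14 to 0.42 over 12 pairs, 3 of them over 0.1. Of the 12, 6 correlated best with their own number. These were replicates 2 and 3 of SUPT11, P12-ICHIKAWA and RPMI-8402, and TALL-1 had no such match. With the replicate number as a block within lines, 4192, 132, 600 and 3603 genes were called in TALL-1, SUPT11, P12-ICHIKAWA and RPMI-8402 and 4770 on average, and with a block across lines 4483, 170, 800, 3890 and 4990. With the 3 arrays left out the counts were 3858, 152, 708, 3417 and 4572. HBB as a covariate left 388 genes in P12-ICHIKAWA, and a fit of the line alone left 33 in SUPT11 and 220 in P12-ICHIKAWA, with fewer residual degrees of freedom. At an adjusted p below 0.01 the counts fell to 107 in SUPT11, 434 in P12-ICHIKAWA and 2389 for the interaction, and to 1926, 874, 474 and 1010 for the differences of TALL-1, SUPT11, P12-ICHIKAWA and RPMI-8402 from the other lines. With a change of at least 1 they were 607, 40, 107 and 517 in the lines, 106 on average, 1062 for the interaction, 443, 198, 127 and 394 for the differences, and 6363 with DMSO. Leaving out single arrays gave 3893 to 4208 genes in TALL-1, 158 to 196 in SUPT11, 586 to 776 in P12-ICHIKAWA, 3254 to 3610 in RPMI-8402, 4733 to 5027 on average, 3370 to 3969 for the interaction, 2611 to 3178, 1284 to 1692, 680 to 980 and 1430 to 2239 for the differences, and 10186 to 10272 with DMSO. Of 640 calls of named genes, 77 were lost with the ACTB covariate, 58 with the HBB covariate, 40 without the 3 arrays and 37 with the block within lines. With the mean of all probe sets, 28 of 612 were lost. Fits of a line alone lost 25 of 36 calls in SUPT11, 46 of 83 in P12-ICHIKAWA, 19 of 167 in TALL-1 and 13 of 152 in RPMI-8402. Of 64 list calls, 4 were lost with the ACTB covariate (proteasome and autophagy in TALL-1, metallothioneins and immediate early genes in P12-ICHIKAWA) and 3 without the 3 arrays (heat shock proteins in SUPT11, ribosomal proteins and immediate early genes in P12-ICHIKAWA). Quantile normalization ended 3 (metallothioneins, ribosomal proteins and immediate early genes in P12-ICHIKAWA), the block within lines 2 (the last 2 of these), and the mean of all probe sets 2 (zinc transporters and oxidative phosphorylation in RPMI-8402). Leaving out single arrays ended 14 of 654, all in lists of 1 line. The mean change turned sign with the mean of all probe sets for PDE10A (0.14 against -0.19) and SLC11A2 (-0.016 against 0.13), and for PSMB5 with the ACTB covariate (0.0083 against -0.15). RAG1 in TALL-1 was -0.84 without the 3 arrays against 1.34, and CD28 on average -0.17 without them, -0.18 without treated TALL-1 replicate 2 and 0.12 without replicate 1, against 0.023. The cause was not tested for these reversals or for HBB as a covariate. Signal over background limits genes near the floor, since any part of a change below the floor is not seen. Their printed changes can also rest on a single array, as for CDK6 in SUPT11 (3.86, but 2.19 without treated replicate 2).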

Other observations

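Single genes of autophagy and of death receptors changed in some lines, while their lists mostly were not called. WIPI1, which acts in autophagosome formation, changed by 2.36 ± 0.20 in TALL-1, 0.96 ± 0.20 in P12-ICHIKAWA and 3.69 ± 0.20 in RPMI-8402 (SE, 3 arrays per group; limma adjusted p = 2.34e-08, 0.00453 and 5.59e-11), and stood at 0.086 ± 0.20 in SUPT11. The autophagy and lysosome list was called in TALL-1 (8 of 17 measured members rose, 8 adjusted over the list alone; camera adjusted p = 0.0294) but not with an estimated correlation (adjusted p = 0.152 with an estimated correlation), and was not called in SUPT11 (camera adjusted p = 0.689), P12-ICHIKAWA (0.475) or RPMI-8402 (0.235). The list of the BCL2 family and death receptors was not called in TALL-1 (camera adjusted p = 0.858), SUPT11 (0.388), P12-ICHIKAWA (0.893) or RPMI-8402 (0.496). TNFRSF10B, a receptor of the death ligand TRAIL, rose in all 4 lines, by 0.87 ± 0.056, 0.22 ± 0.056, 0.50 ± 0.056 and 0.25 ± 0.056 in TALL-1, SUPT11, P12-ICHIKAWA and RPMI-8402. TNFRSF10A was called in TALL-1 alone among the lines (1.88 ± 0.09). BCL2L11, which encodes the pro-apoptotic protein BIM, fell in TALL-1 (-0.49 ± 0.079) and RPMI-8402 (-0.81 ± 0.079), and PMAIP1 was not called in any line.

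Some surface and lineage genes of T cells were lower after treatment. CD2 fell in RPMI-8402 (-3.59 ± 0.13), CD1A in TALL-1 (-2.66 ± 0.11) and P12-ICHIKAWA (-0.55 ± 0.11), and CD8B in TALL-1 (-2.01 ± 0.33). CD8B was uneven in TALL-1 with DMSO (4.32 ± 1.18, SD, n = 3), a spread that the shared standard error understates. Of the 22 measured members of the list of T cell receptor and thymocyte markers, 9 fell in TALL-1, 4 in P12-ICHIKAWA, 7 in RPMI-8402 and 0 in SUPT11, over all genes and adjusted over the list alone. The list was called in TALL-1 (camera adjusted p = 0.00267, but adjusted p = 0.152 with an estimated correlation) and not in P12-ICHIKAWA (0.278), RPMI-8402 (0.192) or SUPT11 (0.636). It was called on average (9 of 22 measured members fell, 9 adjusted over the list alone; camera adjusted p = 0.0122), though not with an estimated correlation (adjusted p = 0.256 with an estimated correlation). Proteasome subunits were lower by small amounts on average (17 of 20 measured members fell, 17 adjusted over the list alone; median -0.084; camera adjusted p = 2.22e-05, but adjusted p = 0.253 with an estimated correlation), as were oxidative phosphorylation genes (11 of 18 measured members fell, 11 adjusted over the list alone; camera adjusted p = 0.00470, but adjusted p = 0.336 with an estimated correlation) and mitotic genes (10 of 22 measured members fell, 10 adjusted over the list alone; camera adjusted p = 0.00889, but adjusted p = 0.256 with an estimated correlation). Fatty acid synthesis rose on average (8 of 9 measured members rose, 8 adjusted over the list alone; camera adjusted p = 0.00127) and cytosolic heat shock proteins fell (7 of 12 measured members fell, 8 adjusted over the list alone; camera adjusted p = 0.00470).

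The other lists were not called on average over the lines. Their camera adjusted p was 0.229 for cytosolic ribosomal proteins, 0.102 for NRF2 targets, 0.577 for p53 targets, 0.940 for the BCL2 family and death receptors, 0.570 for hypoxia and glycolysis, 0.0826 for autophagy and lysosome, 0.940 for iron handling, 0.899 for interferon-stimulated genes, 0.393 for NF-kappaB genes, 0.250 for immediate early genes, 0.570 for T-cell and T-ALL transcription factors and 0.603 for B-cell markers. The test pointed the other way from the median and the mean for the BCL2 family and iron handling, and median and mean differed in sign for the transcription factors. VEGFA, of the hypoxia list, rose in TALL-1 (0.89 ± 0.11), P12-ICHIKAWA (1.03 ± 0.11) and RPMI-8402 (2.01 ± 0.11), and IRF9, of the interferon list, in TALL-1 (1.83 ± 0.28) and RPMI-8402 (1.13 ± 0.28).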
